A study of Mus musculus with 7 samples.

How the data were processed

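RNA was measured by sequencing in 7 mouse hippocampus libraries from translating ribosome affinity purification (TRAP), in which an EGFP-tagged ribosomal protein L10 is made only in cells with Cre recombinase and the tagged ribosomes are pulled down with their RNA. Per the labels, the mice carried Gad2-driven Cre and the tagged protein, and 2 hippocampi were pooled for each TRAP sample. The labels place 3 libraries in the bound group (RNA pulled down with the tagged ribosomes) and 4 in the unbound group. The titles of the bound libraries start with GAD_ctrl, which no unbound title does, so whatever that prefix stands for follows the groups. The titles of the unbound libraries fall into 2 series, UBS and UBGS, with 2 libraries each, and the labels do not say what the series are. Unbound replicates 1 and 2 are the UBS libraries, and replicates 3 and 4 are the UBGS libraries. The labels give no animal, batch or pairing, and do not say that each library came from other animals than the rest, so that p-values measure the spread between these libraries, part of which may be technical.

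The deposited table holds whole-number read counts per gene, not normalized, for 39017 Ensembl gene IDs. Per the submitters' processing notes, STAR 2.5.3a and HTSeq (version not stated) were used with the mm10 build. The annotation release, the strand setting, the treatment of reads that match several places, the read length and the library kit are not given in the sources used here. Some genes had counts identical or almost identical to those of an overlapping or copied gene, and values of genes with near-identical copies, overlapping genes or antisense partners are therefore uncertain. Among the genes named below, the exons of Slc32a1, Htr1b and Csf1r overlapped those of another gene by 24.9%, 18% and 15.1% of their length. IDs were matched without version number to GENCODE M21 (GRCm38, the same assembly as mm10), which named 37607 of them. The other 1410 had no symbol and were kept in the tests under their ID.

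Library totals ranged from 38690380 to 51953811 counts. Pairs of libraries of 1 group differed by 4.42 to 46.3 times the counting variance (chi-square per degree of freedom over genes with at least 20 counts in the pair), so no library appeared to be a second deposit of another. At this depth counting error is small for most named genes, and the spread between libraries sets the precision.

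Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and groups were compared with the quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. A log2 fold change is bound minus unbound, its standard error (SE) was derived from the F statistic, and CPM values were computed here from the TMM-scaled library sizes. No block was fitted. Counts were simulated for 18829 genes with the design of 3 against 4 libraries. The test recovered 75 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 2, with 11 false calls (6.04% of calls). Far fewer genes changed in the simulation than differed in the data, so its share of false calls may not carry over. Adjusted p-values of genes are from edgeR and those of gene lists from camera unless another test is named.

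The comparison between groups, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 30 lists covered markers of GABAergic neurons, of PV, SST, VIP/CCK and neurogliaform interneurons, of excitatory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus and ependyma and meningeal fibroblasts. They also covered GABA-A and ionotropic glutamate receptors, Kv and Nav/Cav/HCN channels, neuropeptides, monoamine and acetylcholine receptors, other neuromodulator receptors, perineuronal net, p11 pathway, immediate early, synaptic vesicle, postsynaptic density, ribosomal protein, mitochondria-encoded, nuclear-encoded oxidative phosphorylation, nuclear noncoding RNA and histone genes. H19, H13 and H1f0, which the name pattern for histones had caught, were removed from that list after the files were read, and 4 fixed members had no row under their symbol. Several genes belong to more than 1 list. Lists were tested with camera in limma 3.58.1 (two-sided, log2 CPM with a prior count of 2, preset correlation between genes of 0.01, adjusted over the 30 lists), with camera at an estimated correlation, and with fry, which asks whether a list moves on balance in 1 direction.

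Named genes are Gad2, Gad1, Slc32a1, Slc17a7 and Rpl10a. To these come the 8 genes with the largest rise and the 8 with the largest fall past the threshold, with a mean of at least 10 CPM and no overlap between the groups' libraries, leaving out predicted, mitochondria-encoded and pseudogene entries. In each list the 2 most abundant members past the threshold in the direction of most such members, and the most abundant in the other direction, are named if their mean reached 1 CPM. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen.

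The alternatives were RLE (DESeq2) size factors, upper-quartile factors, library totals without scaling, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a test against a 1.5-fold minimum (glmTreat), removal of mitochondria-encoded genes, either series of unbound libraries alone, and each library left out in turn. Offsets that remove each library's trend with exon length or GC content, and a run on protein-coding genes without histones, were added after seeing the data. Near-identical copies of 1848 processed pseudogenes were counted with BLAST 2.17.0 (at least 95% identity over at least 50% of the length), and figures were drawn with matplotlib 3.10.9.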

Results

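The data comprised read counts per gene from 3 TRAP-bound and 4 unbound hippocampal libraries. Bound libraries hold RNA pulled down with the tagged ribosomes of cells in which Gad2-driven Cre had acted (Gad2 marks GABAergic neurons). Unbound libraries hold RNA that was not pulled down, and the labels do not say that both kinds came from the same tissue samples. Totals were 47801886, 51953811 and 38690380 counts in bound replicates 1 to 3 and 40465007, 47020568, 47984798 and 46143946 counts in unbound replicates 1 to 4. The comparison asked which transcripts are on ribosomes of the tagged cells more than in the unbound RNA.

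Genes of GABAergic neurons were higher in the bound libraries and genes of excitatory neurons were lower. Gad2, which makes GABA and drives the Cre, stood at 745.5 ± 20.3 CPM in bound libraries (SD, n = 3) and 149.4 ± 42.1 CPM in unbound libraries (SD, n = 4), a 4.99-fold difference (log2 2.32, SE 0.18, edgeR adjusted p = 8.5e-07). That unbound SD spans both title series, at 189.6 and 182 CPM in the UBS and 111.7 and 114.4 CPM in the UBGS libraries. Gad1, the other GABA-synthesizing enzyme, was 7.40-fold higher (522 ± 42.9 against 70.5 ± 7.04 CPM). Slc32a1, which loads GABA into vesicles, was 15.3-fold higher (237.2 ± 17.4 against 15.5 ± 0.961 CPM). Slc17a7, the vesicular glutamate transporter of most excitatory hippocampal neurons, was 34.0-fold lower (14.9 ± 2.38 against 506 ± 21.2 CPM, log2 −5.09, SE 0.12, edgeR adjusted p = 1.8e-10). Rpl10a, which encodes a protein of the large ribosomal subunit, was 1.45-fold higher (210.3 ± 11.4 against 145.5 ± 6.99 CPM).

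On mm10, Gad2 (ENSMUSG00000026787) lies on chromosome 2 from 22622205 to 22693874, Gad1 (ENSMUSG00000070880) on chromosome 2 from 70553072 to 70602014, and Slc32a1 (ENSMUSG00000037771) on chromosome 2 from 158610767 to 158615748. Slc17a7 (ENSMUSG00000070570) lies on chromosome 7 from 45163949 to 45176142 and Rpl10a (ENSMUSG00000037805) on chromosome 17 from 28328471 to 28331033. All 5 are annotated as protein-coding, and the values are for all exons of the gene.

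**Figure D1:**
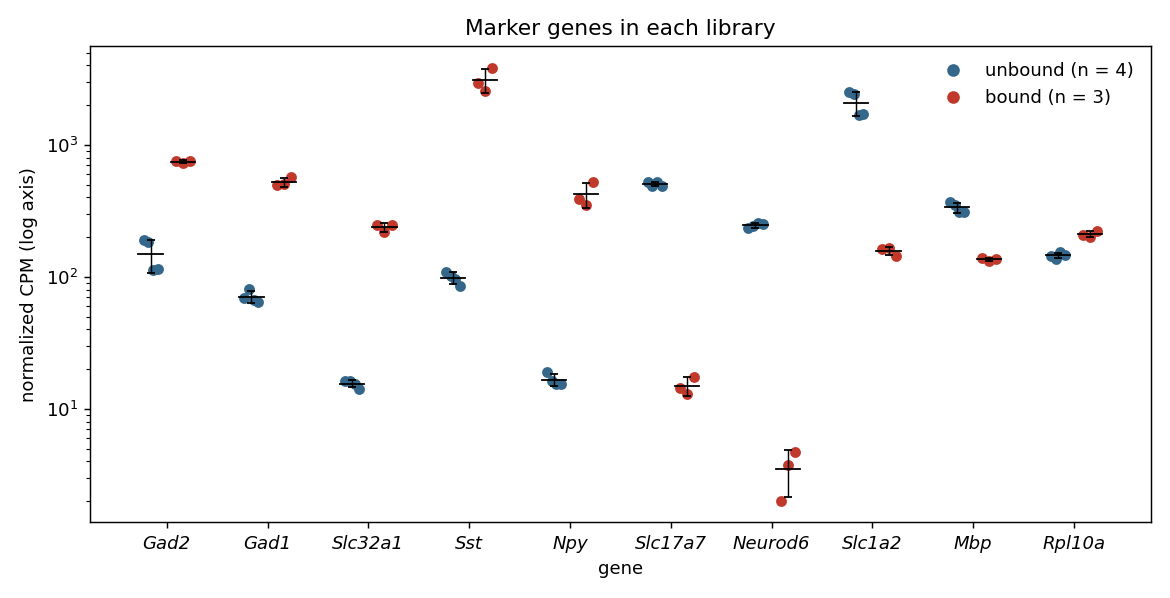
Normalized CPM (log axis) of 10 genes in each of the 4 unbound and 3 bound libraries. Points are libraries, horizontal lines are group means and error bars are SD. Gad2, Gad1, Slc32a1, Sst and Npy were higher in all bound libraries, and Slc17a7, Neurod6, Slc1a2 and Mbp were lower in all of them.

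Of 19563 genes tested, 12076 differed between the groups (edgeR, adjusted p under 0.05), 6072 higher and 6004 lower in bound libraries. At least 2-fold differences were found for 2847 higher and 3478 lower genes. Bound and unbound libraries did not overlap for 63.3% of genes, where chance gives 5.71%. With library totals in place of TMM, the median of all genes moved from −0.01 to 0.43 on the log2 scale and the calls became 9285 higher and 3704 lower (71.5% higher in place of 50.3%), so directions below are relative to the TMM scaling. The test against a 1.5-fold minimum gave 6854 genes, 3246 higher and 3608 lower. Bound and unbound libraries may differ in preparation as well as in the pull-down, which the labels do not settle.

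The 8 named genes with the largest rise included several neuropeptides and receptors. Sst, the peptide of somatostatin interneurons, was 31.8-fold higher (3110 ± 658.4 against 97.9 ± 9.94 CPM, log2 4.99, SE 0.14). Npy (neuropeptide Y) was 25.4-fold, Pnoc (prepronociceptin) 26.9-fold and Tac2 (neurokinin B) 23.9-fold higher. Sncg, a synuclein, was 26.4-fold higher, and Dlx5, a transcription factor of the GABAergic lineage, 20.9-fold. The receptor genes Glp1r and Drd2 were 20.6-fold and 20.1-fold higher, from 2.02 ± 0.280 and 1.13 ± 0.381 CPM in unbound libraries.

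The 8 with the largest fall included transcripts known from excitatory neurons, non-neuronal cells and the nucleus. Neurod6 and Neurod2, transcription factors of excitatory neurons, were 70.9-fold and 54.7-fold lower, and Bdnf, a growth factor made by excitatory neurons, 55.4-fold. Igf2 and Dcn, expressed in the meninges, were 85.3-fold and 40.2-fold lower. Ttr, a choroid plexus transcript, was 78.7-fold lower (log2 −6.30, SE 0.98), with a large spread in bound libraries (15.1 ± 16.9 CPM, and log2 −7.78 without bound replicate 1). The nuclear noncoding RNAs Neat1 and Malat1 were 80.1-fold and 52.9-fold lower, Neat1 at log2 −7.02 without bound replicate 3 against −6.32 with all libraries.

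Of the 30 gene lists, 21 passed camera with the preset correlation and 26 passed fry. With an estimated correlation, only the excitatory neuron and mitochondria-encoded lists passed (adjusted p = 0.0046 each). With fry, all lists passed except the GABA-A receptor, ionotropic glutamate receptor, Nav/Cav/HCN and synaptic vesicle lists (fry adjusted p = 0.15, 0.32, 0.70 and 0.57). Other adjusted p-values of lists are from camera unless fry is named. Counts adjusted over the list alone equalled those over all genes tested except in 3 lists, the ionotropic glutamate receptors (7 higher, 7 lower), the monoamine and acetylcholine receptors (18 higher, 9 lower) and oxidative phosphorylation (74 higher, 1 lower).

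Of 31 GABAergic neuron genes, 28 were higher and 2 lower (median log2 2.70, camera adjusted p = 3.6e-11). With an estimated correlation the adjusted p was 0.094. Cplx1, a complexin that regulates transmitter release, was higher by 1.76 on the log2 scale, while Zeb2, a transcription factor, was lower (−1.04). Among interneuron classes, 13 of 14 SST genes were higher and none lower (median 1.90, adjusted p = 4.7e-06, and adjusted p = 0.094 with an estimated correlation). Of 15 VIP/CCK genes, 13 were higher and 1 lower (median 2.00, adjusted p = 1.5e-05, and adjusted p = 0.094 with an estimated correlation). These included Cnr1, the CB1 cannabinoid receptor (1.83), and Adarb2 (1.89), whereas Prox1, a transcription factor also made by dentate granule cells, was lower (−2.06). Of 12 neurogliaform and ivy cell genes, 10 were higher and 1 lower (median 2.12, adjusted p = 0.00013, and adjusted p = 0.13 with an estimated correlation), with Ndn higher (2.24) and Kit lower (−0.66, a call lost with library totals). Of 18 PV genes, 11 were higher and 5 lower (median 0.94, adjusted p = 0.042, and adjusted p = 0.39 with an estimated correlation). Erbb4, a neuregulin receptor (1.68), and the potassium channel gene Kcnc1 (1.21) were higher and Kcna1, another potassium channel gene, was lower (−1.30). The PV call was lost with library totals, with the UBGS libraries alone, and without unbound replicate 2 or bound replicate 3, at camera adjusted p = 0.12, 0.058, 0.055 and 0.0503, and over all settings the adjusted p ranged from 0.0094 to 0.12.

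Of 36 excitatory neuron genes, 35 were lower and 1 higher (median −3.10, adjusted p = 2.4e-13). Camk2a, a kinase of the postsynaptic density, was lower by 2.06 and Hpca (hippocalcin) by 2.35 on the log2 scale, and Pdzd2 was higher (0.28), a call lost in several settings, among them without unbound replicate 3 or 4 or bound replicate 1 (0.27, 0.24 and 0.22).

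Most other cell types of the hippocampus were lower in bound libraries. Of 20 astrocyte genes, 18 were lower and none higher (median −2.83, adjusted p = 5.2e-07, and adjusted p = 0.20 with an estimated correlation), with Slc1a2, a glutamate transporter, at −3.73. All 18 oligodendrocyte genes tested were lower (median −2.0, adjusted p = 7.0e-08, and adjusted p = 0.13 with an estimated correlation), with the myelin gene Mbp at −1.31. Of 11 precursor genes, 9 were lower, Olig1 (−2.71) among them, and 1, C1ql1, was higher (1.64; median −2.69, adjusted p = 0.00094, and adjusted p = 0.094 with an estimated correlation). Of 18 endothelial and mural genes, 15 were lower and 1 higher (median −2.85, adjusted p = 6.0e-05, and adjusted p = 0.094 with an estimated correlation). Rgs5 and Vtn of the mural cells stood at −2.04 and −3.86 (Vtn at −5.22 without bound replicate 3), and Bsg at 0.95. Of 12 choroid plexus and ependymal genes, 7 were lower and none higher (median −2.11, adjusted p = 0.0018, and adjusted p = 0.32 with an estimated correlation), with Enpp2 at −2.96. All 10 meningeal fibroblast genes were lower (median −4.87, adjusted p = 4.1e-05, and adjusted p = 0.20 with an estimated correlation).

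Microglia genes went the other way, with all 18 higher in bound libraries (median 2.03, adjusted p = 8.2e-05, and adjusted p = 0.38 with an estimated correlation). Csf1r, the receptor for colony-stimulating factor 1, stood at 60.2 ± 34.5 CPM in bound and 17.9 ± 2.81 CPM in unbound libraries (log2 1.75, SE 0.31), and Laptm5 at 69.9 ± 44.7 against 12.5 ± 3.27 CPM (log2 2.48, SE 0.38). Bound replicate 2 held the highest level of each of the 18 genes, for Csf1r 99.1 CPM against 48.5 and 33.1 CPM in replicates 1 and 3. Without it the median was 1.40, Laptm5 stood at 1.825, and 17 of the 18 genes were past the threshold and higher.

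**Figure D2:**
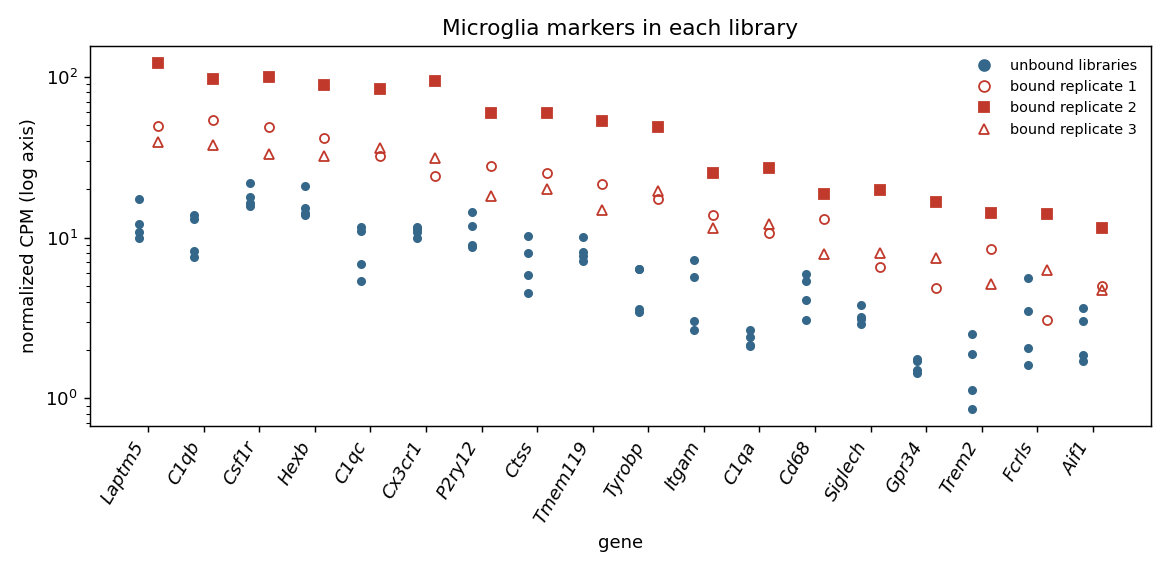
Normalized CPM (log axis) of the 18 microglia list genes in each library, ordered by their mean in bound libraries. Blue points are the 4 unbound libraries and red symbols are bound replicates 1 to 3. Bound replicate 2 (filled squares) is highest for each gene.

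Receptor and channel families were split between the groups. Neuropeptide genes were mostly higher, with 16 of 21 higher and 3 lower (median 1.76, camera adjusted p = 6.4e-05, and adjusted p = 0.094 with an estimated correlation), and Grp, gastrin-releasing peptide, was lower (−3.68). The other receptor and channel lists did not pass camera. The monoamine and acetylcholine receptor, other neuromodulator receptor and Kv lists passed fry (fry adjusted p = 0.00014, 0.00067 and 0.0064). Of 14 GABA-A receptor genes, 7 were higher and 5 lower (adjusted p = 0.90). Of 18 ionotropic glutamate receptor genes, 7 were higher and 6 lower (adjusted p = 0.90), with Grik3 at 1.79 and Grin2b at −1.46. Of 34 monoamine and acetylcholine receptor genes, 18 were higher and 7 lower (adjusted p = 0.06, and 0.035 without bound replicate 3). Htr3a, a serotonin-gated channel, stood at 3.86 and Chrna4, a nicotinic receptor subunit, at 0.85, while Chrm1, a muscarinic receptor, stood at −1.91. Of 29 other neuromodulator receptor genes, 14 were higher and 9 lower (adjusted p = 0.28), with Gabbr1 at 1.17 and Npy2r at −1.96. Of 31 Kv genes, 9 were higher and 13 lower (adjusted p = 0.40), with Kcnq3 at −1.50, and of 17 Nav, Cav and HCN genes 8 were higher and 8 lower (adjusted p = 0.90). The latter list passed with the length offset, at a median of 0.79 in place of 0.18. Scn1a (0.64) was higher there and Cacna1e was lower (−1.52).

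At the synapse, 12 of 25 vesicle genes were higher and 9 lower (adjusted p = 0.73), with Vamp2 at 0.97. Of 21 postsynaptic density genes, 15 were lower and 2 higher (median −0.50, adjusted p = 0.0017, and adjusted p = 0.13 with an estimated correlation), with Nlgn2, a neuroligin of inhibitory synapses, at 0.92. With the length offset the postsynaptic density median was −0.09 and the list no longer passed. Of 15 perineuronal net genes, 9 were lower and 1 higher (median −0.53, adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation), with Ncan at −1.30 and Hapln1, the higher one, at 2.02. That call was lost with the length offset, with library totals and without bound replicate 3, at camera adjusted p = 0.12, 0.057 and 0.0503, over a range from 0.018. Of 9 genes of the p11 pathway, 2 were higher and 5 lower (adjusted p = 0.093), with Htr1b at 0.75 and Ahnak at −3.00. Of 20 immediate early genes, 5 were higher and 8 lower (adjusted p = 0.23), with Dusp1 at 1.09 and Fosl2 and Homer1 at −2.02 and −1.15.

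RNA classes differed between the groups as well. Mitochondria-encoded RNA took 31.3% ± 1.95 of counts in unbound libraries (SD, n = 4) and 0.104% ± 0.018 in bound libraries (SD, n = 3), and all 37 genes were lower (median −6.96, adjusted p = 1.3e-21). Of nuclear-encoded oxidative phosphorylation genes, 73 of 82 were higher and 1 lower (median 1.38, adjusted p = 5.6e-19, and adjusted p = 0.13 with an estimated correlation), with the ATP synthase genes Atp5b and Atp5a1 at 0.39 each. All 8 nuclear noncoding RNAs tested were lower (median −4.12, adjusted p = 4.0e-05, and adjusted p = 0.094 with an estimated correlation), Meg3 by 3.56 on the log2 scale. Their median was −3.50, −3.53 and −3.45 without unbound replicate 4, bound replicate 1 and bound replicate 2, where 7, 9 and 9 of the RNAs were tested. Of 83 cytosolic ribosomal protein genes, 49 were higher and 8 lower (median 0.33, adjusted p = 4.1e-05, and adjusted p = 0.32 with an estimated correlation), with Rpl41 at 1.42 and Rpl4 at −0.66. With the length offset that median was 0.10 and the list no longer passed. Of 57 histone genes, 49 were higher and 1 lower (median 1.57, adjusted p = 2.9e-12, and adjusted p = 0.13 with an estimated correlation), with Hist1h4d at 1.83 and Hist2h2be at −1.23. With the length offset the oxidative phosphorylation and histone medians were 0.96 and 1.17, and both lists still passed.

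Fold changes also varied with exon length, taken over all annotated exons of a gene merged. Over 15087 protein-coding genes, the median log2 fold change was 0.93 for exon lengths under 1000 nucleotides and −0.49 from 8000 nucleotides up (Spearman rho −0.31 across genes, which are not independent replicates). Processed pseudogenes took 3.95% ± 0.130 of counts in bound and 1.72% ± 0.087 in unbound libraries, and 848 of 1760 were higher and 184 lower. Ribosomal protein and histone genes have many near-identical copies, and their values are uncertain for that reason. Gm42418, which overlaps ribosomal RNA sequence, took 13.3% ± 2.04 of counts in bound and 5.05% ± 1.07 in unbound libraries.

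**Figure D3:**
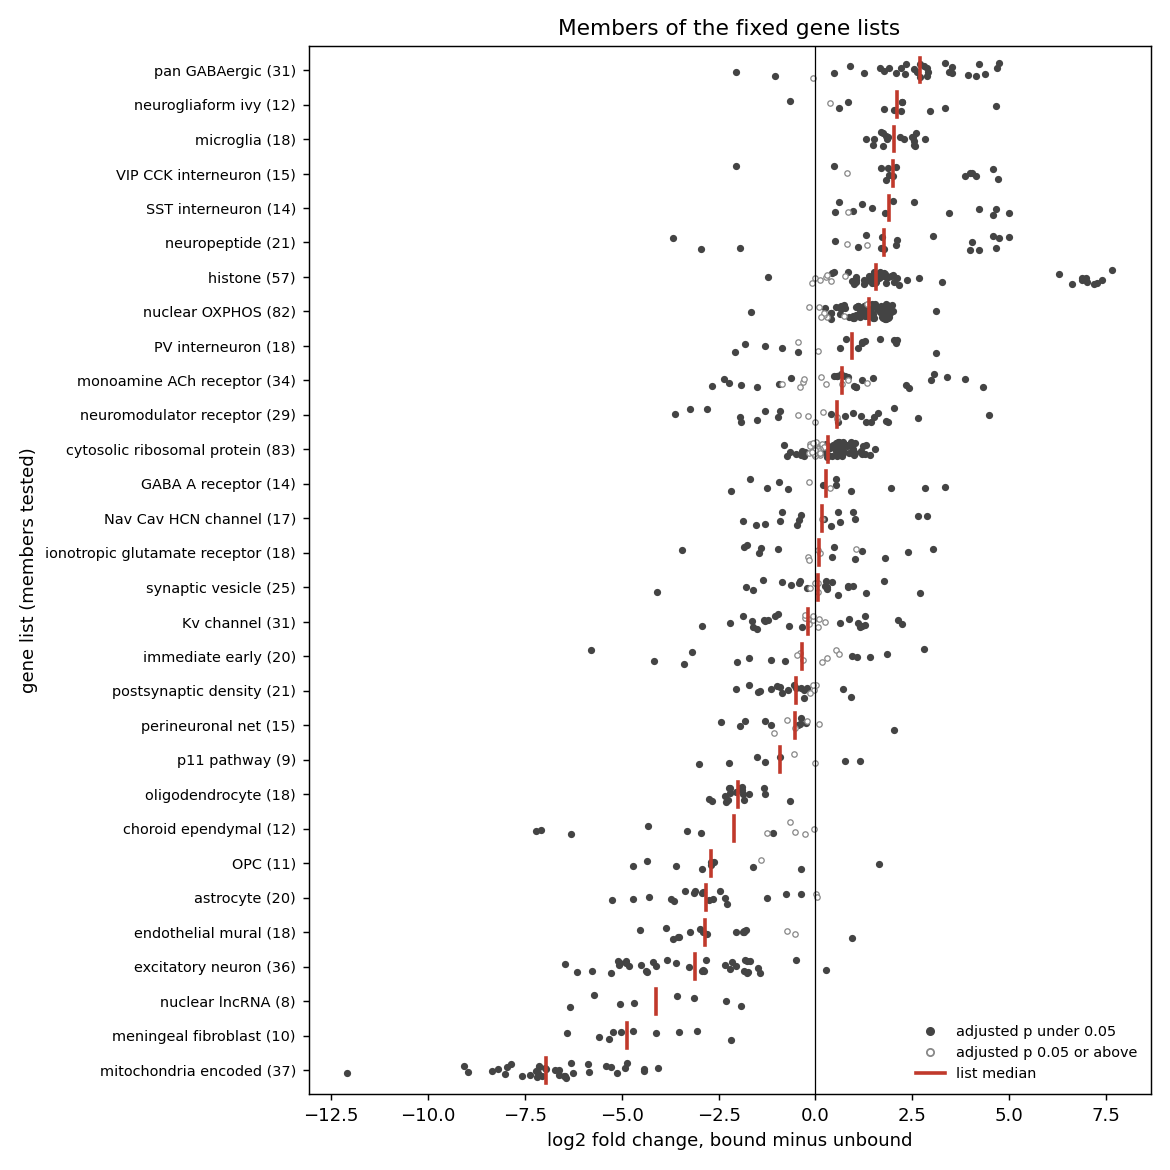
Log2 fold change (bound minus unbound) of the members of the 30 gene lists, ordered by list median. Filled points passed an adjusted p of 0.05 (edgeR), open points did not, and red bars are medians. Kcnj8 and mt-Tv, at 0 counts in all bound libraries, are not drawn. The GABAergic list has a median of 2.70 and the excitatory list a median of −3.10.

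The 4 unbound libraries were compared by title series, because a difference inside that group would widen the main comparison. Of 19256 genes, 44 differed between the 2 UBS and the 2 UBGS libraries, 18 higher and 26 lower in UBS (edgeR, adjusted p under 0.05), and 3232 had an unadjusted p under 0.05. Gad2 was the only named gene among them, at 163.2 ± 4.56 CPM in UBS (SD, n = 2) and 99.4 ± 1.54 CPM in UBGS libraries (SD, n = 2), scaled within the 4 libraries (log2 0.72, SE 0.06, edgeR adjusted p = 0.022). Gad1 (log2 0.18, edgeR adjusted p = 0.37) and Slc32a1 (log2 0.13, edgeR adjusted p = 0.57) did not pass, and the median of the GABAergic list was −0.001. Among genes chosen after their values were seen, Cwc22, a splicing factor, was lower in UBS (14.8 ± 0.887 against 118.5 ± 2.36 CPM), as was Cck (log2 −1.28), and the major histocompatibility genes H2-D1 and H2-K1 were higher (1.28 and 1.34). Medians of the microglia, choroid plexus and ependymal, and astrocyte lists were 0.53, 0.44 and 0.43 higher in UBS, with 0, 0 and 1 members past the threshold, and medians of the other lists lay from −0.15 to 0.23. DESeq2 called 301 genes, and leaving out unbound replicates 1, 2, 3 and 4 in turn gave 4684, 7389, 16 and 19, with the lone library of a series assumed to vary like the others. Gad2 did not pass without unbound replicate 3 or 4 (log2 0.70 and 0.73, edgeR adjusted p = 0.19 and 0.068). With replicate 1 or 2 left out, the spread comes from the UBGS pair alone, which differed by 4.42 times the counting variance against 20.1 times for the UBS pair. With either series alone as the unbound group, 9868 (UBS) and 10762 (UBGS) genes differed from the bound libraries.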

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

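The test of the GABAergic share was chosen after the result was seen. For 4 named genes, 1 of the 4 unbound libraries lay far from the other 3, among 120 sets of 4 values examined, where chance gives about 6. Hapln4 was at 114.6 CPM in unbound replicate 1 against 79.0 to 83.1 in the others, and Tnr at 57.9 CPM in replicate 1 against 48.9 to 50.2. Ndn was at 38.0 CPM in replicate 2 against 63.9 to 67.7, and Scn1a at 95.9 CPM in replicate 2 against 119.7 to 123.9.

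Gad2 differed between the UBS and UBGS libraries by 0.715 on the log2 scale, and 43 other genes differed with it. A different share of GABAergic neurons in the series is argued against, since the median difference of the other 30 GABAergic genes was −0.003. Its 95% bootstrap interval, −0.06 to 0.03, was drawn over genes and does not measure the spread between libraries. A candidate explanation for some of these genes is that the mice differ in strain or genotype at linked loci. Called genes on chromosomes 1 to 19 and X, counted once where counts in the 4 unbound libraries were identical, numbered 36. Of these, 11 lay within 2 Mb of another, where the 95th percentile of 10000 random sets was 8. Part of that comes from near-identical gene copies on chromosome 2, and without them 9 of 34 genes had such a neighbour against a 95th percentile of 6. Gad2 had no called gene within 2 Mb, so the test does not bear on Gad2 itself. Linked sequence copies and batches that follow the series were not separated from genotype, since the labels do not say what the series are.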

How the results depend on the processing

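The length offset, the GC offset and the run on protein-coding genes without histones were chosen after seeing the data. Under the 21 settings, 1681 values of named genes kept their direction and side of the threshold, 45 lost the call and 7 reversed, and for list medians these numbers were 608, 9 and 4, with 5 that gained a call. The count of genes between bound and unbound libraries stayed within 1.5 times of 12076 except against a 1.5-fold minimum (6854, with 3246 higher and 3608 lower). With library totals 9285 were higher and 3704 lower, and of the 12989 genes called 9832 were also called with TMM. Leaving out 1 library gave 10861 to 11831 genes. With an estimated correlation 2 lists passed in place of 21.

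With library totals, the Kv list median reversed to 0.25 and the immediate early median to 0.090, and Atp1b2 (0.072), Cplx2 (0.035), Hapln4 (0.052), Shank1 (0.067) and Tnr (0.077) reversed, which the shift of 0.43 in the median of all genes accounts for in size. With the length offset, the Kv median (0.034), Shank1 (0.17) and Tnr (0.28) reversed. With the GC offset the Nav, Cav and HCN median reversed to −0.14. The cause of these reversals was not tested further. The ribosomal protein, postsynaptic density and perineuronal net lists lost their call with the length offset, at medians of 0.10, −0.09 and −0.47. The monoamine and acetylcholine receptor list gained a call in 4 settings.

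Between UBS and UBGS libraries, 44 genes became 104 without a low-count filter, 301 with DESeq2, 22 in a model of all 7 libraries, and 16 to 7389 when 1 library was left out. The highest counts (4684 and 7389, without unbound replicates 1 and 2) take their spread from the UBGS pair alone (biological coefficient of variation 0.035 against 0.19 from the UBS pair). The cause of the other moves was not tested. No paired analysis was possible because the labels give no animal or day that ties bound to unbound libraries. The numbers in the titles of the bound libraries do not occur in those of the unbound libraries.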

Other observations

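Genes in the first 2 paragraphs were chosen after their values were seen, as were the tests of carry-over, of blood and of parent genes over all pseudogenes. Zic family transcription factors were higher in bound libraries, Zic1 at 206.7 ± 55.4 against 10.6 ± 1.51 CPM (log2 4.28), Zic4 at 3.78, Zic2 at 3.12 and Zic5 at 3.15. Reln, the reelin gene, was at 228.6 ± 28.9 against 29.5 ± 2.49 CPM, Vip at 59.1 ± 9.69 against 3.73 ± 0.935 CPM and Pvalb at 54.2 ± 11.7 against 13.4 ± 0.916 CPM. Fos was higher (log2 2.81, SE 0.28) while Arc was not past the threshold (−0.33, SE 0.18). S100a10, which encodes p11, was higher (1.16, SE 0.19).

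Small nuclear and nucleolar RNAs went the way of the nuclear noncoding RNAs, with 30 of 43 snoRNA genes lower and none higher, and 14 of 17 snRNA genes lower and 1 higher.

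The 12076 genes that differed between bound and unbound libraries were set against other splits of the 7 libraries into 3 and 4. Only the real split, 1 of 35, gave as many. The highest of the others was 0 genes at the adjusted threshold with edgeR, the only tool run on the splits. At an unadjusted p under 0.05 it was 5791. Every other split puts bound and unbound libraries in the same group, so their difference widens the spread and few calls were likely in advance. The splits therefore cannot exclude chance for the count.

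Microglia genes were higher in bound libraries while astrocyte, oligodendrocyte and endothelial genes were lower. Carry-over of bulk RNA is argued against, since it could not lift a transcript above its unbound level and the median was 2.03. The 95% bootstrap interval, 1.75 to 2.54, was drawn over the 18 genes and does not measure the spread between libraries. The argument against carry-over assumes that the unbound libraries show the bulk level of the bound samples. The labels do not say that both came from the same tissue. A single library is not the whole source, since the median without bound replicate 2 was 1.399 with 17 of 18 genes past the threshold. The median of 5 red cell genes was −4.261 (−3.64 without bound replicate 2 and −7.874 without bound replicate 3), so red cell RNA was not enriched in bound libraries. Genes of most other cell types were lower there too, so this does not tell how much blood the tissue held. No list of white blood cell genes was tested. Of macrophage genes, chosen after their values were seen, Cd163 (−3.16) and Lyve1 (−1.63) were lower. Mrc1, Pf4, F13a1, Cbr2 and Stab1 were not past the threshold. All of these macrophage genes had group means of 4.015 CPM or below, so they decide little. Immune genes chosen likewise were split, with Ighm higher (2.32) and Igkc (−4.16) and Cd74 (−1.57) lower. Blood stays open. Tagged ribosomes made in microglia, RNA from microglia that sticks to the beads, and preparation that differed between the groups stay open and were not tested.

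More processed pseudogenes were higher than lower in bound libraries, 848 and 184 of 1760, with a median log2 fold change of 0.62. A candidate explanation for the class is that its parent genes are enriched and their reads spill onto the copies: over all 1673 with a parent gene, transcribed ones included, pseudogenes exceeded their parents by a median of only 0.122 (95% bootstrap interval 0.066 to 0.198), at medians of 0.621 and 0.421. Intervals for pseudogenes were drawn over parent genes, not over libraries. The small difference cannot tell spilled reads from a trend with exon length that pseudogenes and parents may share, and this was not tested. The largest rises are left open. The 227 pseudogenes above a log2 fold change of 2 exceeded their parents by a median of 2.963, but picking them for their rise lifts that value, so the test fixed in advance on them decides nothing. The largest was Gm13292 (similar to Gapdh, with 74 near-identical copies), higher by 9.97 on the log2 scale, with 7 to 16 counts in unbound and 14441 to 18424 in bound libraries. Reads that match many copies may have been kept or placed differently in the 2 kinds of library, but the test fixed in advance did not show it: pseudogenes with 5 or more copies exceeded those with none by 0.255, and the interval, −0.04 to 0.61, includes 0, the outcome written beforehand as counting against this explanation. It is left open, since the interval also reaches past the 0.5 written as its mark, and since a division made after the values were seen gave a median of 2.17 for 183 pseudogenes with 20 or more copies, from 15 parent genes, against 0.62 for 455 with none and 0.42 for 243 with 5 to 9. Of 14 Hist1h2a genes, which are near-identical copies too, 11 were over 32-fold higher in bound libraries.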
